A study of Danio rerio with 8 samples.

How the data were processed

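RNA from bodies of adult wild-type zebrafish, without head and fins, was hybridised to custom Agilent arrays by the authors: 8 arrays in 4 groups of 2, for control and for 20, 40 and 80 ppb arsenic trioxide over 30 days. Per the labels, the fish were 4 to 5 months old and had 15 days of acclimatisation, RNA of 3 fish was pooled, and 500 ng was labelled with Cy3. Both arrays of a group name 1 pool, and the series design calls them technical replicates, while the treatment protocol speaks of 3 fish per replicate. Groups were taken from the sample titles. The description of 20 ppb replicate 2 says 80 ppb, but its title, source name and pool say 20 ppb, and it was kept in the 20 ppb group. Per the file headers all arrays lie on 1 slide, with control and 20 ppb in row 1 and 40 and 80 ppb in row 2, so a term for the row could not be fitted beside the groups.

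Per the file headers, the scanner files hold intensity values that Agilent Feature Extraction 11.5.1.1 made with protocol GE1_1105_Oct12: background was subtracted, trends across the array were removed, and values were not scaled between arrays. The authors also deposited a table of log2 values, in which the 75th percentile of each array lies near 0 (from the values); its columns run against log2 of the processed intensity with slopes of 0.994 to 0.997 and a Pearson r across probes of 0.997 to 0.9988. Each array has 62976 spots, 61657 of them not controls, for 43041 probes, and no spot was saturated. Between 62.9% and 75.4% of spots were well above background per the software's own test. The number of arrays limits the precision.

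From the scanner files, spots marked as outliers were left out, log2 of the processed intensity was averaged over the spots of a probe, and the 75th percentile of each array was subtracted. Probes were kept when well above background on both arrays of at least 1 group, which left 31006 probes, and 181 were dropped for missing values. Probes were named from the supplied gene table: 22077 by accession, 9935 by symbol, 3414 by gene number and 1697 by synonym, and 5918 kept the name in the file. The brightest probe by mean over the 8 arrays stood for its gene, giving 19650 genes. No genome came with the series, so no probe positions are given. The software was R 4.3.3 with limma 3.58.1 and the package data.table (version 1.17.8), and python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

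All 8 arrays entered 1 limma fit of 4 groups (lmFit, contrasts.fit and eBayes; 4 residual and 1.94 prior degrees of freedom), with 6 contrasts: each dose against control and each dose against each other dose. P-values were two-sided and Benjamini-Hochberg adjusted over all genes of a contrast, and a gene changed where the adjusted p was under 0.05. A fold was given as "at least" where the dimmer group was well above background on neither array. The brighter mean was then compared with the higher, per array, of the lowest signal well above background and the probe's own signal. Fits at the level of pools used the mean of the 2 arrays per pool, for a linear trend with dose and for 3 exposed pools against 1 control pool. Gene lists, 29 of pathways and 19 of tissues, 48 in all, were tested with limma's camera with a preset correlation of 0.01 and adjusted over the 48 lists, again with an estimated correlation, and with limma's fry, which asks whether the genes of a list move on balance one way or, in its mixed form, in either direction, and does not compare the list with other genes.

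Groups, comparisons, lists, the alternatives named first below and the rule for naming genes were fixed before the data were examined. The rule took, per comparison with control, the 8 largest rises and 8 largest falls among genes with a proper symbol that passed the test, had no overlap between the arrays of the groups and were well above background on both arrays of the higher group. It also took 2 to 4 members of each described list with the largest change past the test, the 5 smallest p in each direction of the pool fits, and mt2, hmox1a, as3mt, gclc, hsp70l, vtg1 and cyp1a in every comparison. Some genes this rule took are not reported here. Alternatives were quantile normalization, scaling to the array median, normexp background with an offset of 50, the authors' table, no filter, a filter on all 8 arrays, the mean of all probes of a gene, a minimum of 2-fold, eBayes with trend and robust, only the 4 arrays compared, a replicate block, leaving out each array, and, for pools, all arrays with no pool term or with the pool as a random block, the rank of the dose and leaving out each exposed pool. Scaling to spike-in probes, array brightness as a covariate, a crossed pairing of replicates and slide row as a covariate of the pools were chosen after seeing the data. Because the 3 comparisons with control share its arrays, overlaps were set beside 100 simulated sets of 8 arrays without group differences. In these the doses shared simulated control arrays. Their noise came from the differences between the 2 arrays of a group, so they held no spread between pools. With 2 arrays the control group could not be split. The pipeline was tested on simulated data with known changes. There 19450 of 19650 genes were unchanged and the noise was the spread between arrays of a group. In the 3 comparisons with control it recovered 0 of 66 changes of 1.41-fold and 0 or 1 of 67 of 2-fold. Of 67 changes of 4-fold it recovered 23 to 25. A gene that did not pass may therefore still differ.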

Results

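Adult wild-type zebrafish (Danio rerio) were kept for 30 days in water with arsenic trioxide at 20, 40 or 80 ppb, or without it, and RNA of bodies without head and fins was measured on 1-colour microarrays. Each of the 4 groups had 2 arrays, 8 in all, and the labels trace both arrays of a group to 1 pool of 3 fish. The number of arrays limits the precision. The series calls the arrays of a group technical replicates, so a p-value below compares RNA pools against the spread between arrays, not between fish. The labels do not give the sex of the fish. Control and 20 ppb lie in 1 row of the slide and 40 and 80 ppb in the other, so outside the comparisons of 20 ppb with control and of 80 with 40 ppb, the row and the group cannot be told apart. After dim probes were left out, 19650 genes remained, 14847 of them with a gene symbol. Between 62.9% and 75.4% of the spots of an array were well above background, and the 75th percentile of the signal ran from 237 (40 ppb replicate 2) to 1062 (control replicate 1). Agreement was taken across the 15758 genes well above background on all 8 arrays, which are not independent replicates. The Spearman correlation of both arrays of a group was 0.969 for control, 0.984 for 20 ppb, 0.937 for 40 ppb and 0.994 for 80 ppb. Replicate 1 of 40 ppb correlated better with the 20 ppb arrays (0.956 and 0.969) than with its own replicate. Over the same genes the median SD between the arrays of a group was 0.33, 0.19, 0.38 and 0.07 log2 units in the same order. Changes below are log2 differences relative to each array's 75th percentile, with the SE from limma and n = 2 arrays per group. A gene rose, fell or changed where its limma adjusted p passed the threshold of 0.05, and a list did where its camera adjusted p passed it.

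The comparison of 20 ppb with control asks which transcripts of the body differ after 30 days at the lowest dose. Most measured genes of the eye and pituitary list and of the nerve list rose. Among the 8 largest rises, the one well above background on all arrays was that of epd, which encodes ependymin, a glycoprotein of the fish brain fluid, at 65.5-fold (log2 6.03 ± 0.42, SE, n = 2 arrays per group, limma adjusted p = 0.00136). The stress genes hmox1a, heme oxygenase, and hsp70l, an inducible heat shock protein, rose 4.34-fold (log2 2.12 ± 0.31, adjusted p = 0.0098) and 1.995-fold (log2 0.996 ± 0.205, adjusted p = 0.0266). Collagen, cell cycle, ovary and DNA repair lists fell, but no list passed with an estimated correlation (smallest adjusted p = 0.0701). Lists of liver, skeletal muscle and skin markers rose, although their medians turned negative with spike-in scaling (-0.04, -0.09 and -0.21).

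Transcription factors that neuronal activity induces rose in npas4a (log2 5.36, at least 19-fold) and egr4 (5.31, 39.6-fold, with control well above background on 1 array). The glutamate receptor subunit gria2b rose 38.5-fold (5.27), with control above background on 1 array, and the secreted neuronal protein lgi3 rose at least 55.6-fold (7.49). Beyond these, dcaf13, a ubiquitin ligase adaptor with a part in ribosomal RNA processing, rose at least 137-fold (9.26). The MHC class I gene mhc1uha rose at least 120-fold (9.05 ± 0.40, adjusted p = 0.000736), and tnfrsf14, a TNF receptor family member, at least 12.1-fold (5.88). Ribosome assembly gene ppan fell at least 34.7-fold (-7.44), and lto1, which acts with an iron-sulfur protein of ribosome recycling, fell 32.5-fold (-5.02). The phosphate-regulating peptidase phex fell 49.2-fold (-5.62), while its 2 other probes stood at -0.40 and -0.27 and did not pass. Recombination repair gene xrcc2 fell at least 7.48-fold (-5.04). The brightest probe of hccsa.1, a cytochrome c heme lyase, fell at least 21.9-fold (-5.03), but its other 3 probes went the opposite way (3.6 to 4.21). Cargo receptor cnih4 fell 31.4-fold (-4.97), with 20 ppb above background on 1 array, and the transcription cofactor sertad3 at least 6.86-fold (-4.92). Of the genes named in every comparison, none of the rest passed. The log2 changes were 0.43 for the metallothionein mt2 (adjusted p = 0.593), 0.69 for the arsenic methyltransferase as3mt (0.185), -0.22 for the glutathione synthesis enzyme gclc (0.489), 0.29 for the yolk precursor vtg1 (0.62) and 0.12 for the arylhydrocarbon target cyp1a (0.841).

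Of the 33 measured members of the list for head, eye, pituitary and brain, tissues of which the body samples should hold little, 21 rose and none fell at 20 ppb (25 and 0 adjusted over the list alone). The list median was 1.48, but 0.77 with spike-in scaling, and the camera adjusted p = 5.65e-10, with adjusted p = 0.0701 with an estimated correlation. The green cone opsin opn1mw1 rose at least 16.6-fold (4.79), the pituitary hormone subunit lhb at least 4.83-fold (4.04), growth hormone gh1 by 3.26 and the hypothalamic peptide avp by 2.34. Among 27 spinal cord and nerve markers, 18 rose and none fell (20 and 1 adjusted over the list alone). The median was 1.59, but 0.88 with spike-in scaling (adjusted p = 3.9e-07, and adjusted p = 0.076 with an estimated correlation). Among these, syt1b was at least 3.41-fold higher (3.89), with rises of 2.98 in syn1, 2.97 in the neuronal RNA-binding elavl3 and 2.96 in stxbp1a. Skeletal muscle markers rose in 10 and fell in 1 of 44 (15 and 2 adjusted over the list alone). The list had a median of 0.62 (adjusted p = 0.00351, and adjusted p = 0.277 with an estimated correlation). The myosin gene myhz1.1 rose by 2.77, the troponin tnni2a.1 by 1.495 and tnnc1b by 1.28. Liver markers rose in 6 of 30 and fell in none (9 and 1 adjusted over the list alone), led by the plasma proteins ahsg1 (1.90), serpina1 (1.42) and fetub (1.06). The median stood at 0.67 (adjusted p = 0.0102, and adjusted p = 0.224 with an estimated correlation). Skin markers rose in 3 of 26 and fell in none (5 and 0 adjusted over the list alone), with the keratin krt96 at 1.39 and the cornified envelope gene evpla at 0.78. The median change was 0.50 (adjusted p = 0.0196, and adjusted p = 0.224 with an estimated correlation).

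The cell cycle list fell at 20 ppb with a median of -0.41 over 46 members, of which 2 rose and 2 fell (0 and 1 adjusted over the list alone; adjusted p = 0.000386, and adjusted p = 0.224 with an estimated correlation). The mitotic activator cdc20 fell by 1.25 and the condensin subunit ncapg by 0.63, while the replication helicase genes mcm6 and mcm3 rose by 1.04 and 1.03. In the collagen and matrix list, 5 of 33 members fell and 1 rose (6 and 1 adjusted over the list alone). The members had a median of -0.23 (adjusted p = 0.0196, and adjusted p = 0.323 with an estimated correlation). The collagen crosslinking enzyme lox fell by 2.58, col11a2 by 1.35, col5a2b by 1.27 and col1a1b by 1.15. Ovary and oocyte markers fell as a list (median -0.34 over 35, adjusted p = 0.0196, and adjusted p = 0.411 with an estimated correlation). Of these, the aromatase gene cyp19a1a fell by 1.63 and the egg envelope gene zp3f.1 rose by 1.26, 1 gene each way, as when adjusted over the list alone. DNA repair fell with a median of -0.17 over 39 members, where 2 fell and none rose (2 and 0 adjusted over the list alone; adjusted p = 0.0218, and adjusted p = 0.224 with an estimated correlation), namely xrcc2 and brca2 (-1.02). The remaining 39 of the 48 lists did not pass with camera. Of all 48 lists, 37 passed with fry, which tests whether the genes of a list move on balance one way, and 41 passed its mixed test for change in either direction.

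In total 3169 genes changed at 20 ppb, 2287 higher and 882 lower. With no filter on dim probes 2011 changed. An unadjusted p under 0.05 was found for 6098, where arrays of 1 common pool would give 982.5 on average. The arrays did not overlap in any called gene, nor in 57.2% of all genes, where such arrays would give 33.3%. Both reference values leave out differences between pools of fish, so an excess over them does not speak for exposure. The higher share was 72.2%, but 57.6% with quantile normalization, 37.2% with scaling to the median, 15.4% with spike-in scaling and 55.3% with array brightness as a covariate. The count was 606 and 756 without 20 ppb replicates 1 and 2, 1508 and 1782 without control replicates 1 and 2, 1528 without either 80 ppb replicate, 1219 with normexp background, 6591 with spike-in scaling, 12369 with array brightness as a covariate, 8966 with the crossed pairing and 1333 with only the 4 arrays compared, all of which lie in 1 row of the slide.

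The comparison of 40 ppb with control puts the same question to the middle dose. The lists of head and of nerve markers rose again, with medians that shrank to 0.32 and 0.57 with spike-in scaling, but no list passed at 40 ppb with an estimated correlation (smallest adjusted p = 0.112). The gene hmox1a rose 5.08-fold (log2 2.35 ± 0.31, SE, n = 2 arrays per group, limma adjusted p = 0.00597), hsp70l 3.20-fold (1.68, adjusted p = 0.00485) and as3mt, which methylates arsenic, 2.25-fold (1.17, adjusted p = 0.0367). Liver, muscle, skin, intestine, complement and ribosomal protein lists rose, with medians that all turned negative with spike-in scaling (-0.02, -0.10, -0.12, -0.16, -0.24 and -0.34). Lists of cell cycle, ovary, germ cell, DNA repair, protein folding stress and glucocorticoid response genes fell, all with the preset correlation only.

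Among single genes at 40 ppb, mhc1uha rose at least 318-fold (log2 10.46). The immunoproteasome subunits psmb9b and psmb8f, which trim peptides for MHC class I, fell at least 25.8-fold each (-6.97 and -6.90, adjusted p = 0.00105 for both). Related genes went the other way: psmb8a rose by 2.74, psmb9a by 2.27, psmb12 by 2.72 and psmb13a by 2.705, while psmb10 (0.15) did not pass. These related genes were chosen after their values were seen. The glutamate receptor subunits gria1b and gria2b rose at least 43.2-fold (7.64 ± 1.70, adjusted p = 0.025) and 33.8-fold (5.08, with control well above background on 1 array), epd 33.3-fold (5.06) and opn1mw1 at least 18.7-fold (4.97). Other large rises were those of the macrophage perforin mpeg1.3 (5.51, at least 12.5-fold), the fucosyltransferase fut9a (4.91, at least 6.19-fold) and the lysosome regulator tfe3b (4.89, at least 6.32-fold). The ribosome assembly gene ppan fell at least 23.3-fold (-6.62). Falls were also seen in zbtb3, a zinc finger gene, at 32.7-fold (-5.03, with 40 ppb above background on 1 array), in vstm2lb at least 22.8-fold (-4.97), in the iodide transporter slc5a5 at least 5.29-fold (-4.64) and in scospondin, of the spinal canal fibre, at least 4.94-fold (-4.58). The genes named in every comparison that did not pass were mt2 (0.55, adjusted p = 0.409), gclc (-0.36, 0.198), cyp1a (1.08, 0.0579) and vtg1 (0.28, 0.573), which passed in the opposite direction with spike-in scaling (-0.58, adjusted p = 0.0498).

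At 40 ppb 18 of 33 head, eye and pituitary members rose and 1 fell (22 and 1 adjusted over the list alone). The list median was 1.18 (adjusted p = 8.39e-06, and adjusted p = 0.112 with an estimated correlation). Beside opn1mw1, avp rose by 2.2 and the lens genes lim2.1 and cryba2a by 1.99 and 1.73. Of 27 nerve markers, 17 rose and none fell (19 and 0 adjusted over the list alone), led by elavl3 (2.98), stxbp1a (2.81) and the axonal stmn2a (2.71). Their median was 1.43 (adjusted p = 8.94e-06, and adjusted p = 0.112 with an estimated correlation). Liver markers rose in 13 of 30 and fell in 1 (15 and 1 adjusted over the list alone). The median was 0.84 (adjusted p = 0.00055, and adjusted p = 0.116 with an estimated correlation). The iron hormone hamp rose by 3.42, serpina1l by 1.69, ahsg1 by 1.43 and the amino acid enzyme tat by 1.34. Skeletal muscle rose in 18 of 44 and fell in 2 (19 and 2 adjusted over the list alone), with tnni2a.1 at 1.94 and myhz1.1 at 1.90, while the slow myosin smyhc1 fell at least 2.12-fold (-2.21). The list had a median of 0.76 (adjusted p = 0.000953, and adjusted p = 0.201 with an estimated correlation). In skin 7 of 26 rose and none fell (10 and 0 adjusted over the list alone), krt17 by 1.72 and cyt1l by 1.58. The median stood at 0.74 (adjusted p = 0.00118, and adjusted p = 0.116 with an estimated correlation). In intestine 10 of 26 rose and 1 fell (12 and 1 adjusted over the list alone), with the brush border gene vill at 2.56 and the chitinase chia.2 at 1.26. The median change was 0.70 (adjusted p = 0.00475, and adjusted p = 0.171 with an estimated correlation). Of 29 complement and acute phase genes, 8 rose and none fell, as when adjusted over the list alone (median 0.62, adjusted p = 0.00742, and adjusted p = 0.171 with an estimated correlation), among them masp2 (1.99), serpinf2a (1.2) and the acute phase protein saa (1.2). The ribosomal protein list rose with 1 of 76 members past the test, rpl36a at 1.03, and none adjusted over the list alone (median 0.52, adjusted p = 0.00334, and adjusted p = 0.663 with an estimated correlation).

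Of 46 cell cycle genes 16 fell and 3 rose at 40 ppb (19 and 3 adjusted over the list alone). The members had a median of -0.62 (adjusted p = 2.24e-05, and adjusted p = 0.116 with an estimated correlation). The mitotic ligase ube2c fell at least 1.75-fold (-2.47), the cohesion factor cdca5 by 2.07 and the condensin smc2 by 1.48, while mcm3 rose by 2.005. Ovary markers fell in 5 of 35 and rose in none (4 and 0 adjusted over the list alone), with cyp19a1a down at least 1.95-fold (-2.53), zp3d.1 at -1.11 and btg4 at -0.84. The list median was -0.62 (adjusted p = 2.31e-05, and adjusted p = 0.201 with an estimated correlation). Germ cell markers fell with 1 of 10 members past the test, the transposon silencer piwil2 (-1.03), and none adjusted over the list alone (median -0.59, adjusted p = 0.00742, and adjusted p = 0.171 with an estimated correlation). In DNA repair 7 of 39 fell and 1 rose, as when adjusted over the list alone (median -0.55, adjusted p = 0.00118, and adjusted p = 0.116 with an estimated correlation): xrcc3 fell by 1.53, the base excision gene apex1 by 1.46 and the checkpoint kinase chek2 by 1.24, while the glycosylase ogg1 rose by 1.58. The list for the unfolded protein response fell in 7 of 33 and rose in 2, as when adjusted over the list alone (median -0.52, adjusted p = 0.000953, and adjusted p = 0.201 with an estimated correlation). The stress sensor eif2ak3 fell by 1.29 and sdf2l1 by 1.03, whereas ddit3, a stress-induced transcription factor, rose by 1.44 and the chaperone dnajb9a by 1.26. Of 18 glucocorticoid response genes 8 fell and 1 rose (8 and 2 adjusted over the list alone): the metabolic kinase pdk2b fell by 3.39, the receptor co-chaperone fkbp5 by 2.98, the collagenase mmp13a by 2.39 and sgk2b by 1.61. Their median was -0.86 (adjusted p = 0.0383, and adjusted p = 0.201 with an estimated correlation). Of all 48 lists 34 did not pass with camera, while 36 passed with fry and 46 with its mixed test.

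At 40 ppb 5086 genes changed, 3303 higher and 1783 lower, and 7936 had an unadjusted p under 0.05. Arrays of both groups did not overlap in 55.2% of all genes, where arrays of 1 common pool would give 33.3%. The higher share was 64.9%, but 54.4% with quantile normalization, 33.2% with scaling to the median, 14.3% with spike-in scaling and 51.9% with array brightness as a covariate. The count was 2313 and 3252 without control replicates 1 and 2, 3028 without either 20 ppb replicate, 2590 without either 80 ppb replicate, 3099 with normexp background, 8483 with spike-in scaling, 13322 with array brightness as a covariate and 0 with only the 4 arrays compared (limma, 4737 at an unadjusted p under 0.05).

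**Figure D1:**
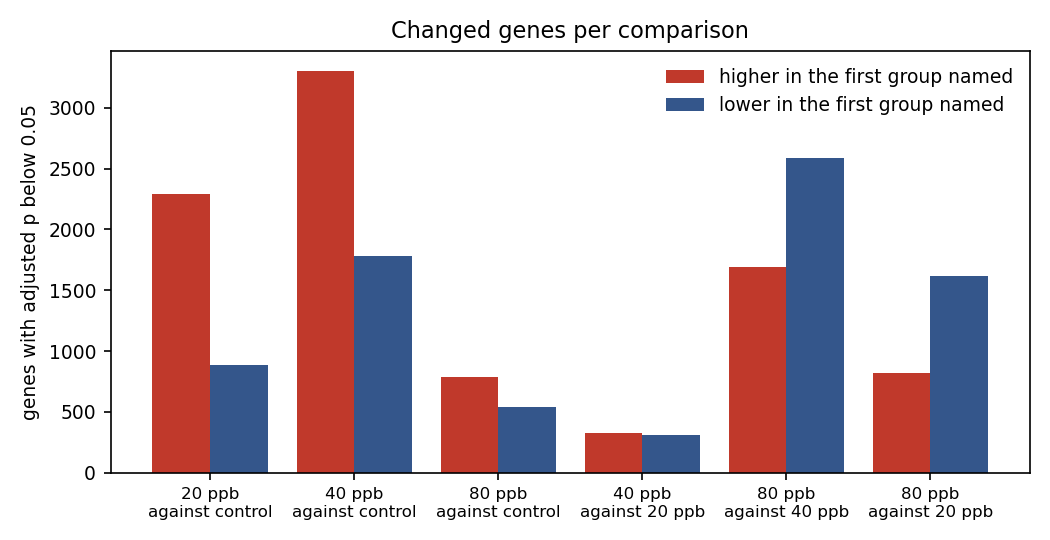
The vertical axis gives the number of genes with a limma adjusted p under 0.05 and the bars give those higher and lower in each of the 6 comparisons between groups of 2 arrays. The most genes are at 40 ppb against control (3303 higher, 1783 lower) and the fewest at 40 against 20 ppb (326 and 307). This order depends on the fit, which shares 1 spread per gene among groups of unequal spread. The median SD between arrays was 0.38 at 40 ppb and 0.07 at 80 ppb. With only the 4 arrays compared, the count was 0 at 40 ppb against control and highest at 80 against 20 ppb (6021). Which direction has more genes turned with scaling to the median in every comparison and with spike-in scaling in all but 80 ppb against control. At 80 ppb against control it also turned with quantile normalization or normexp background. At 40 against 20 ppb it also turned with quantile normalization, with array brightness as a covariate (3734 higher, 4550 lower) and without some single arrays. At 80 against 20 ppb it also turned without 20 ppb replicate 1.

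At 80 ppb, the highest dose, hmox1a and hsp70l did not pass against control, at log2 changes of 0.55 (limma adjusted p = 0.439) and 0.30 (0.553), and neither did as3mt at 0.25 (0.8). The gene cyp1a, a target of the arylhydrocarbon receptor, rose by 1.78 ± 0.32 (SE, n = 2 arrays per group, limma adjusted p = 0.032), with control well above background on 1 array. Digestive enzymes of the exocrine pancreas fell as a list, and so did collagens, glucocorticoid response and gluconeogenesis genes. None of these lists passed with an estimated correlation, where the smallest adjusted p of all lists was 0.174. Of 27 nerve markers 8 rose, and of 5 pituitary and 10 lens genes 3 and 1, and epd rose 57.8-fold (5.85, adjusted p = 0.00308).

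Large single rises at 80 ppb included dcaf13 at least 141-fold (9.30), tnfrsf14 at least 34.7-fold (7.40) and the steroid hormone regulator nr5a1b at least 24.1-fold (5.89). The respiratory complex I subunit ndufs8b rose at least 18.5-fold (5.83, adjusted p = 0.00195), the cell survival gene api5 at least 9.06-fold (5.40), the repressor her8a at least 7.86-fold (5.22) and the guanine exchange factor mcf2a at least 13.5-fold (4.90). The ileal bile acid carrier slc10a2 fell at least 17.0-fold (-6.37), sertad3 at least 7.95-fold (-4.60) and the Golgi protein golm1 at least 4.52-fold (-4.49). One probe of tsga10, a spermatid gene, fell 20.1-fold (-4.33, adjusted p = 0.000678) while the other stood at 1.22. Further falls were those of the actin regulator eps8l1b at 19.2-fold (-4.26) and the anion exchanger slc26a4 at least 6.86-fold (-3.82). Of the genes named in every comparison, mt2 (0.03, adjusted p = 0.993), gclc (0.27, 0.558) and vtg1 (-0.28, 0.806) did not pass either.

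In the exocrine pancreas list 7 of 25 members fell and none rose at 80 ppb (12 and 0 adjusted over the list alone). The median was -0.66 (adjusted p = 6.66e-10, and adjusted p = 0.261 with an estimated correlation). The elastases cela1.5 and ela2 fell by 2.51 and 1.41, and the carboxypeptidase cpb1 by 1.19. Collagen and matrix genes fell (median -0.39 over 33, adjusted p = 0.000269, and adjusted p = 0.305 with an estimated correlation), with 1 member past the test, col1a1b (-1.31), and 1 rising and 6 falling adjusted over the list alone. The glucocorticoid response list had 4 falls and 1 rise in 18 (6 and 1 adjusted over the list alone): fkbp5 fell by 2.80 and pdk2b by 2.5, sgk2b fell at least 3.76-fold (-2.01), and the stress-induced ddit4 rose by 3.17. The list had a median of -0.54 (adjusted p = 0.000711, and adjusted p = 0.204 with an estimated correlation). Gluconeogenesis and glucose genes fell in 3 of 25 and rose in 1 (5 and 1 adjusted over the list alone), where the rate-setting enzyme pck1 fell by 2.58 and the phosphatase g6pc1a.2 by 2, while the glycogen phosphorylase pygmb rose by 0.96. The median stood at -0.18 (adjusted p = 0.0244, and adjusted p = 0.312 with an estimated correlation). Muscle markers fell in 2 of 44 and rose in none, as when adjusted over the list alone (median -0.24, adjusted p = 0.0437, and adjusted p = 0.35 with an estimated correlation): the oxygen store mb fell by 1.70 and the myosin myhz2 by 1.22. The muscle call was lost with quantile normalization (camera adjusted p = 0.0765) and with the filter on all arrays (0.0631). It was also lost without control replicate 1 or either 80 ppb replicate.

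Nerve markers rose at 80 ppb in 8 of 27 and fell in none (14 and 0 adjusted over the list alone), with syn1 at 2.26, stxbp1a at 2.01 and stmn2a at 1.73. The median change was 0.70 (adjusted p = 1.23e-06, and adjusted p = 0.174 with an estimated correlation). The head, eye and pituitary list rose in 6 of 33 and fell in none (9 and 0 adjusted over the list alone), among them lhb at least 5.59-fold (4.25), gh1 (2.98) and opn1mw1 at least 2.44-fold (2.03). The members had a median of 0.43 (adjusted p = 0.000516, and adjusted p = 0.204 with an estimated correlation). The other 41 lists did not pass with camera, while 28 passed with fry and 26 with its mixed test.

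At 80 ppb 1329 genes changed, 791 higher and 538 lower, and 3790 had an unadjusted p under 0.05. Arrays did not overlap in 49.6% of all genes, where arrays of 1 common pool would give 33.3%. The higher share was 59.5%, but 49.0% with quantile normalization, 46.6% with scaling to the median and 41.3% with normexp background. The count was 91 and 100 without 80 ppb replicates 1 and 2, 609 and 512 without control replicates 1 and 2, 631 without either 20 ppb replicate, 303 with normexp background, 739 with no filter on dim probes, 8199 with array brightness as a covariate and 628 with only the 4 arrays compared.

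**Figure D2:**
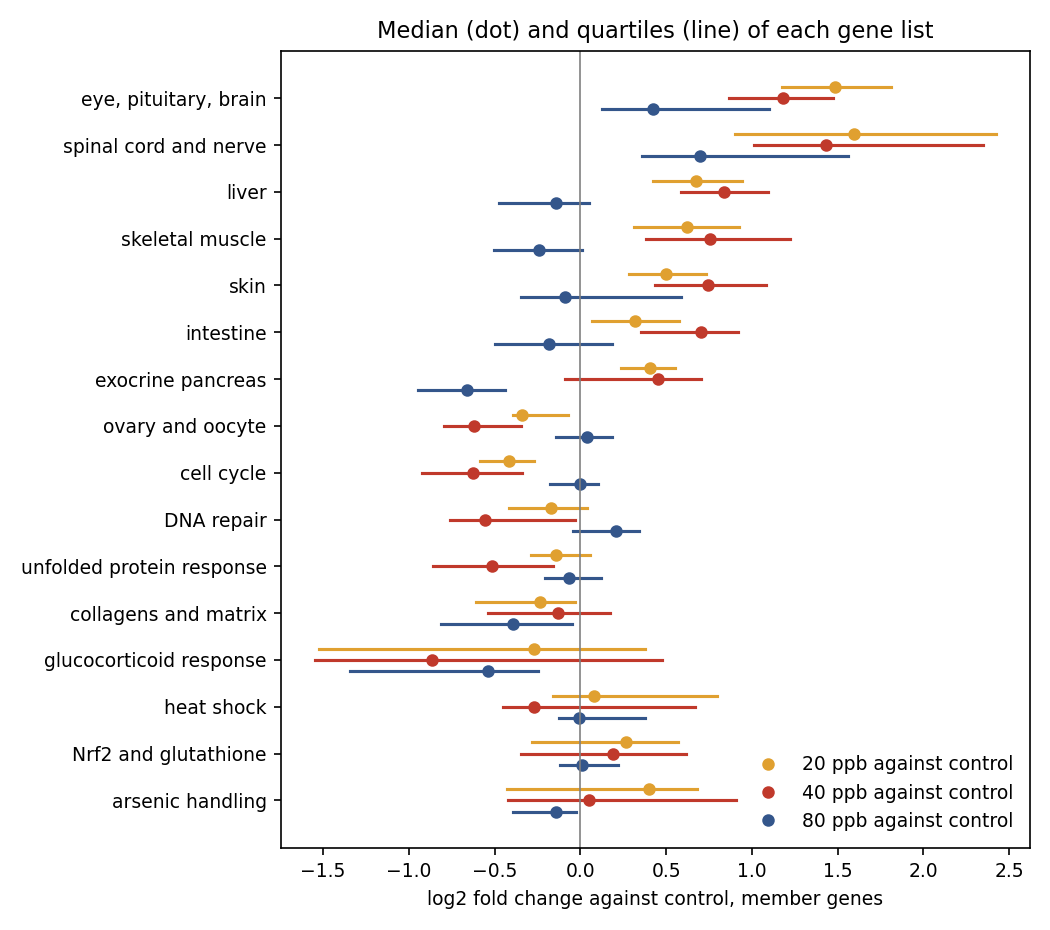
The horizontal axis gives the log2 change against control and each dot is the median of 1 gene list at 20, 40 or 80 ppb, with a line from the lower to the upper quartile of its members. Head and nerve lists lie highest at 20 ppb (1.48 and 1.59) and of the 80 ppb medians that of exocrine pancreas lies lowest (-0.66), while with spike-in scaling the medians of liver, muscle, skin, intestine, pancreas, glutathione and arsenic lists at 20 and 40 ppb and of heat shock at 20 ppb turned negative, with scaling to the median those of glutathione at all doses, of intestine and heat shock at 20 ppb and of arsenic at 40 ppb did so, and some near 0 at 80 ppb changed sign.

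The lists of glutathione and Nrf2 targets, heat shock, arsenic handling and metal binding did not pass with camera at any dose, although single members changed. In the list of glutathione and Nrf2 targets, 1 rose and 2 fell of 24 at 20 ppb, 3 rose and 5 fell at 40 ppb, and 1 rose and 2 fell at 80 ppb, with the same counts adjusted over the list alone. The medians were 0.27, 0.19 and 0.01, and turned to -0.07, -0.185 and -0.15 with scaling to the median and, at 20 and 40 ppb, to -0.445 and -0.67 with spike-in scaling. The means were 0.08, 0.14 and 0.04, and the camera direction was down at all doses (adjusted p = 0.754, 0.873 and 0.905). Beside hmox1a, the autophagy receptor sqstm1 fell by 1.73 at 20 ppb, the peroxidase partner srxn1 rose by 1.62 and the glutathione transferase gstm.1 fell by 2.40 at 40 ppb, and gsr fell by 1.21 and prdx1 rose by 1.07 at 80 ppb. Of 28 heat shock genes 7 rose and none fell at 20 ppb, 6 rose and 2 fell at 40 ppb, and 1 fell at 80 ppb, as when adjusted over the list alone. The heat shock median at 20 ppb was 0.08 (adjusted p = 0.344), but -0.26 with scaling to the median and -0.64 with spike-in scaling. The small heat shock proteins cryaba and cryabb rose by 1.74 and 1.41 at 20 ppb and by 1.79 and 1.62 at 40 ppb, while the regulator hsf2 fell by 1.83 at 40 ppb. At 40 ppb the heat shock median was -0.27, its mean 0.10 and its camera direction down (adjusted p = 0.828), and at 80 ppb the median was -0.01 (0.09 with quantile normalization), the mean 0.07 and the direction up (0.905). In the list of arsenic uptake, methylation and export 2 rose and 1 fell of 27 at 20 ppb (1 and 1 adjusted over the list alone), 5 rose and 3 fell at 40 ppb and none passed at 80 ppb, both as when adjusted over the list alone (camera adjusted p = 0.933, 0.828 and 0.0702). The arsenic medians at 20 and 40 ppb were 0.40 and 0.05, but -0.31 and -0.81 with spike-in scaling, and that at 40 ppb -0.32 with scaling to the median. The exporter abcc5 rose by 1.08 at 40 ppb, where as3mt rose too. The exporter abcc1 fell at least 2.59-fold at 20 ppb (-1.86) and at least 1.74-fold at 40 ppb (-1.34, but 0.20 in the authors' table). Among 21 metal-binding genes 4 rose at 20 ppb and 6 at 40 ppb, and 1 fell at 80 ppb (4, 6 and 0 adjusted over the list alone; camera adjusted p = 0.282, 0.452 and 0.575). The metallothionein-like mtbl rose by 1.54 and 1.75 at 20 and 40 ppb, and the copper pump atp7b by 0.92 and 2.23, and hamp rose by 3.42 at 40 ppb.

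**Figure D3:**
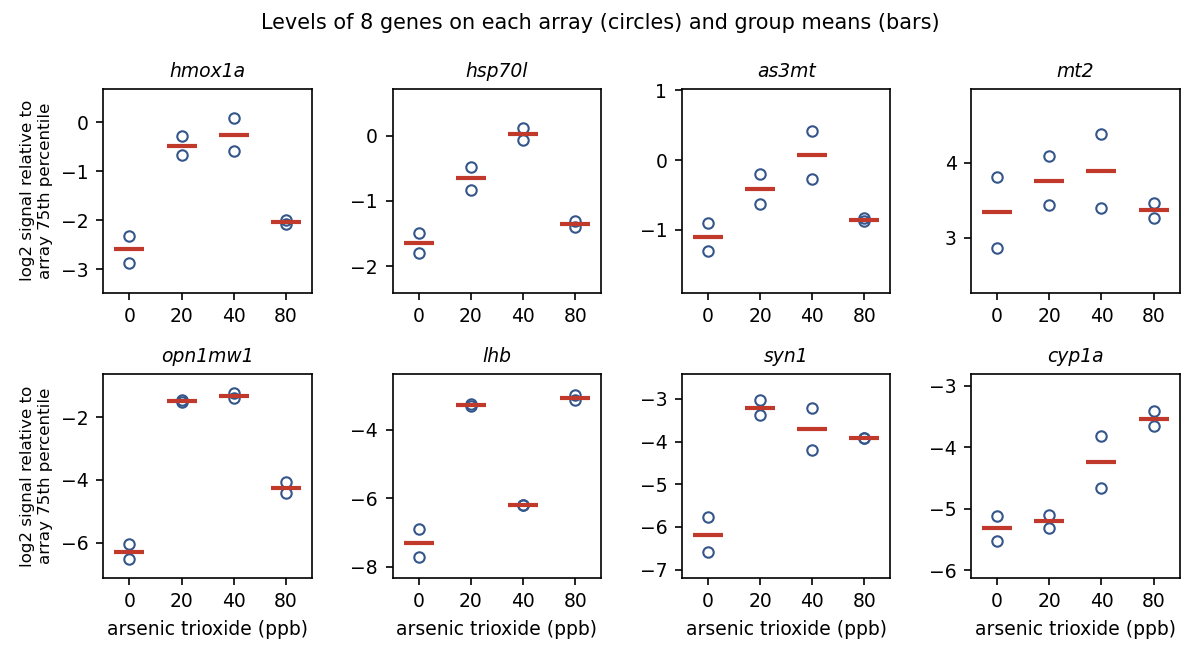
The horizontal axes give the dose in ppb and the vertical axes the log2 signal relative to the array's 75th percentile for 8 genes, with a circle per array and a bar at each group mean. Means of hmox1a are -2.60 in control, -0.48 at 20 ppb, -0.25 at 40 ppb and -2.04 at 80 ppb, while those of lhb are -7.30, -3.27, -6.20 and -3.06.

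The comparisons between doses ask whether the responses differ, and the control arrays enter their fit through the spread between arrays. Between 40 and 20 ppb 633 genes differed, between 80 and 40 ppb 4281 and between 80 and 20 ppb 2443. At 80 ppb hmox1a was lower than at 40 ppb (-1.79 ± 0.31, SE, n = 2 arrays per group, limma adjusted p = 0.017) and than at 20 ppb (-1.57, 0.0297). The change of hsp70l was -1.38 against 40 ppb (0.0119), and -0.70 against 20 ppb did not pass (0.0814). In contrast cyp1a was higher at 80 than at 20 ppb (1.67 ± 0.32, adjusted p = 0.0282, with 20 ppb well above background on 1 array). Muscle, pancreas and liver markers fell and ovary, cell cycle and DNA repair genes rose as lists from 40 to 80 ppb, but none passed with an estimated correlation (smallest adjusted p = 0.124), and the falls shrank to medians of -0.06, -0.19 and -0.09 with spike-in scaling.

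From 20 to 40 ppb 633 genes changed, 326 higher and 307 lower, and 3232 had an unadjusted p under 0.05. With a replicate block 316 changed. Genes past the test with large measured differences, not all of them exact, were phex (5.90), lto1 (4.82), xrcc2 (4.72, at least 5.995-fold), dcaf13 (-8.26, at least 64.7-fold), lgi3 (-6.94, at least 26.2-fold) and psmb8f (-6.08, at least 14.6-fold), chosen here after their values were seen. Ovary (median -0.31), unfolded protein (-0.32) and immediate early genes (-0.31) fell, and intestine (0.40) and kidney (0.30) rose, with camera adjusted p = 0.00422, 0.0307, 0.0407, 0.0157 and 0.0461, and adjusted p = 0.476 with an estimated correlation for each. Of their members 2 rose in intestine, 1 rose in kidney, 1 fell in immediate early, 1 rose and 1 fell in unfolded protein and none passed in ovary. Adjusted over the list alone, the falls were 5 in immediate early and 4 in unfolded protein, and the rest the same. The pituitary genes lhb and gh1 were lower at 40 ppb (-2.93, at least 2.28-fold, and -2.86, with 40 ppb well above background on 1 array). For the fixed genes the changes were 0.13 for mt2 (adjusted p = 0.93), 0.23 for hmox1a (0.797), 0.49 for as3mt (0.508), -0.15 for gclc (0.778), 0.68 for hsp70l (0.169), -0.01 for vtg1 (0.991) and 0.96 for cyp1a (0.214). The count was 41 and 62 without 20 ppb replicates 1 and 2, 339 without 40 ppb replicate 2, 153 without either 80 ppb replicate, 96 with normexp background, 259 with no filter, 8284 with array brightness as a covariate, 1426 with the crossed pairing and 1 with only the 4 arrays compared (limma, 2049 at an unadjusted p under 0.05).

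From 40 to 80 ppb 4281 genes changed, 1695 higher and 2586 lower, and 7912 had an unadjusted p under 0.05. With a replicate block 2844 changed. The genes dcaf13 (8.30, at least 66.5-fold), ppan (7.05, at least 31.3-fold), psmb8f (6.46, at least 19.1-fold) and psmb9b (6.45, at least 18.1-fold) were among the rises, and mhc1uha (-10.20, at least 259-fold), gria1b (-7.42, at least 35.2-fold) and slc10a2 (-7.06, at least 27.5-fold) among the falls, chosen here after their values were seen. Of 44 muscle markers 23 fell and 1 rose (28 and 1 adjusted over the list alone), with the calcium pump atp2a1l at -1.78 and actn3a at -1.81. The list median was -0.999 (adjusted p = 5.37e-07, and adjusted p = 0.127 with an estimated correlation). Exocrine pancreas fell in 14 of 25 and rose in none (18 and 0 adjusted over the list alone), with a median of -1.13 (adjusted p = 5.06e-06, and adjusted p = 0.152 with an estimated correlation). Liver markers fell in 11 of 30 and rose in none (12 and 0 adjusted over the list alone; median -1.02, adjusted p = 2.14e-05, and adjusted p = 0.124 with an estimated correlation), with serpina1l at -2.5 and cp at -1.69. With spike-in scaling the medians of muscle, pancreas and liver were -0.06, -0.19 and -0.09. Ovary rose in 8 of 35 and fell in none (11 and 0 adjusted over the list alone), with the egg gene zar1 at 1.38. Their median was 0.63 (adjusted p = 2.71e-06, and adjusted p = 0.148 with an estimated correlation). Cell cycle genes rose in 13 of 46 and fell in 2 (20 and 2 adjusted over the list alone), with a median of 0.58 (adjusted p = 6.63e-05, and adjusted p = 0.126 with an estimated correlation). DNA repair genes rose in 8 of 39 and fell in none, as when adjusted over the list alone (median 0.53, adjusted p = 4.07e-05, and adjusted p = 0.124 with an estimated correlation). In all 19 lists passed with camera, 5 up and 14 down, and none with an estimated correlation. The changes of the fixed genes that did not pass were -0.53 for mt2 (adjusted p = 0.429), -0.92 for as3mt (0.0743), 0.63 for gclc (0.0594), -0.56 for vtg1 (0.268) and 0.71 for cyp1a (0.157). The higher share was 39.6%, but 63.2% with scaling to the median and 92.4% with spike-in scaling. The count was 118 and 152 without 80 ppb replicates 1 and 2, 1939 without 40 ppb replicate 2, 1596 without either 20 ppb replicate, 2670 with normexp background, 1986 with no filter, 8063 with spike-in scaling, 12629 with array brightness as a covariate and 58 with only the 4 arrays compared, which lie in 1 row of the slide.

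From 20 to 80 ppb 2443 genes changed, 822 higher and 1621 lower, and 5921 had an unadjusted p under 0.05. With a replicate block 1567 changed. Pancreas genes fell in 14 of 25 and rose in none (17 and 0 adjusted over the list alone), with ela2 at -2.26 and cela1.5 at -2.25. Their median was -1.1 (adjusted p = 1.84e-08, and adjusted p = 0.116 with an estimated correlation). Muscle genes fell in 13 of 44 and rose in none (27 and 1 adjusted over the list alone; median -0.91, adjusted p = 1.31e-06, and adjusted p = 0.107 with an estimated correlation), with myhz1.1 at -2.10. With spike-in scaling the pancreas and muscle medians were -0.31 and -0.12. Head markers fell in 10 of 33 and rose in none (15 and 0 adjusted over the list alone), with opn1mw1 at -2.76. The head median was -0.79, but 0.00 with spike-in scaling (adjusted p = 3.64e-05, and adjusted p = 0.107 with an estimated correlation). Immediate early genes fell in 9 of 34 and rose in none (11 and 0 adjusted over the list alone), with klf4 at -2.83 (at least 4.69-fold) and fosb at -2. The immediate early median was -0.69, but 0.10 with spike-in scaling (adjusted p = 8.53e-05, and adjusted p = 0.107 with an estimated correlation). In all 18 lists passed with camera, 4 up and 14 down, and none with an estimated correlation. Changes of the other fixed genes were -0.40 for mt2 (adjusted p = 0.609), -0.44 for as3mt (0.377), 0.49 for gclc (0.147) and -0.57 for vtg1 (0.324). The higher share was 33.6%, but 55.2% with scaling to the median, 91.4% with spike-in scaling and 45.7% with array brightness as a covariate. The count was 103 and 128 without 80 ppb replicates 1 and 2, 152 and 201 without 20 ppb replicates 1 and 2, 990 with normexp background, 1195 with no filter, 6021 with only the 4 arrays compared, 6406 with spike-in scaling, 11713 with array brightness as a covariate and 8821 with the crossed pairing.

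Shared changes were counted across the doses against the common control pool. At all 3 doses 510 genes rose and 119 fell, 629 of the 6132 that changed at any dose. The 629 became 342 with no filter on dim probes, and 415 with the filter on all 8 arrays or with a replicate block. The gene epd rose throughout (6.03, 5.06 and 5.85 at 20, 40 and 80 ppb), as did ndufs8b (4.85, 4.56 and 5.83), npas4a (5.36, 4.69 and 3.99), gria2b (5.27, 5.08 and 3.87) and the Notch target her4.4 (4.44, 4.37 and 3.71). Throughout, sertad3 (-4.92, -4.41 and -4.60), eps8l1b (-3.99, -4.12 and -4.26) and vstm2lb (-4.71, -4.97 and -3.61) fell. In control ndufs8b, npas4a and her4.4, in all exposed groups sertad3, and at 40 ppb vstm2lb, were not well above background, so their differences are not exact. At 20 and 40 ppb 1904 genes were both higher and 493 both lower, where independent draws give 384.4 and 80, and 46 went opposite ways. At 20 and 80 ppb 569 and 177 were shared (92.1 and 24.1), with 54 opposite, and at 40 and 80 ppb 599 and 225 (133 and 48.8), with 59 opposite. In 100 simulated sets of unchanged groups with a shared simulated control the shared counts averaged 0.1 to 1.3. The most for 20 and 40 ppb were 69 higher and 93 lower. The simulated noise was the spread between arrays of a group. A control pool that differs from the other pools was not simulated, so the counts it would give are not known. Across genes the correlation of the log2 changes was 0.747 for 20 and 40 ppb, 0.484 for 20 and 80 ppb and 0.454 for 40 and 80 ppb, and the simulated sets gave 0.39, 0.507 and 0.442 on average from the shared control alone, and at most 0.994, 0.998 and 0.991. The median simulated set called 0 genes at each dose (limma), but single sets called up to 11908, 11186 and 35 at 20, 40 and 80 ppb. The count of 629 was 45 without either 80 ppb replicate, 227 and 237 without 20 ppb replicates 1 and 2, 307 and 293 without control replicates 1 and 2, 96 with normexp background, 3942 with array brightness as a covariate and 0 with only the 4 arrays compared.

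Fits on the 4 pools, each the mean of its 2 arrays, ask which genes follow the dose and which differ in the exposed pools, with the pool as the replicate. No gene passed for the trend with dose (limma, 0 genes). An unadjusted p under 0.05 was found for 527, 256 rising and 271 falling, below the 982.5 expected by chance. In other settings 51 passed without the 20 ppb pool and 25 with slide row as a covariate, both with 1 residual degree of freedom before moderation. With all 8 arrays and no pool term 27 passed, a fit that takes the arrays of a pool as replicates. The smallest p rising with dose were those of api5 (1.42 log2 units per 20 ppb), the thiamine phosphatase thtpa (1.1), hmbox1b (0.87), fam32a (0.84) and nr5a1b (1.59), and among those falling were nfil3-3 (-1.64), znfl2a (-0.78), golm1 (-1.13) and the growth kinase mtor (-0.87), each with adjusted p = 1. In control api5, hmbox1b and nr5a1b, and at 80 ppb nfil3-3, golm1 and mtor, lay below the lowest signal well above background. Their slopes are therefore not exact. Of the fixed genes the slopes were 0.48 for cyp1a, 0.08 for gclc, 0.04 for as3mt and hsp70l, 0.03 for hmox1a, -0.01 for mt2 and -0.09 for vtg1. For 3 exposed pools against 1 control pool, which is assumed to vary like the others, no gene passed (limma, 0 genes; 1324 at an unadjusted p under 0.05, 1092 higher and 232 lower, smallest adjusted p = 0.283). That count was 119 with the pool as a random block, 644 with all 8 arrays and no pool term, 109 without the 20 ppb pool, 252 without the 40 ppb pool and 104 with slide row as a covariate. The fit had little power in simulated data, where it recovered 0 of 67 4-fold changes and 39 of 67 that were 16-fold. Those data held the spread between arrays but none between pools, so its power for these pools is not known. The smallest p belonged to epd (5.65), her4.4 (4.17), the chemokine ccl39.6 (4.22), ndufs8b (5.08) and ndufb11 (3.91) on the higher side, and to sertad3 (-4.64), eps8l1b (-4.12), pax1a (-3.26), slc26a4 (-3.45) and vstm2lb (-4.43) on the lower. There the fixed genes stood at 1.67 for hmox1a (limma adjusted p = 0.841), 0.99 for hsp70l and cyp1a, 0.70 for as3mt, 0.34 for mt2, 0.10 for vtg1 and -0.10 for gclc. As lists, exocrine pancreas had a median slope of -0.19 per 20 ppb (adjusted p = 7.46e-10, and adjusted p = 0.982 with an estimated correlation), although its median lay above control at 20 and 40 ppb (0.405 and 0.455, and -0.31 and -0.405 with spike-in scaling) and below it at 80 ppb (-0.66). For exposed pools the nerve and head lists had medians of 1.26 and 1.04 (adjusted p = 0.999 with an estimated correlation for both), where the spread of the 1 control pool is not known. With fry no list passed for either fit, apart from 1 in the mixed test for exposed pools.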

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

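Spike-in scaling, array brightness as a covariate, the crossed pairing and slide row as a covariate were chosen after seeing the data, and the other settings beforehand. Under quantile normalization, scaling to the median, the authors' table, the mean of all probes and eBayes with trend and robust, all counts of changed and shared genes stayed within 1.5 times. So did the counts of lists in the comparisons with control. List counts between doses and for the pools were not taken under these settings. The pool fits had 0 changed genes (limma) there, but the fit of exposed pools recovered 0 of 67 simulated 4-fold changes. Of the values of named genes under an alternative, 7176 kept their direction and side of the threshold, 2617 kept the direction and lost the call, 15 gained it, 25 uncalled values changed sign and 16 values called in at least 1 of the settings compared reversed. Of the list values 2747 kept both, 71 lost the call, 115 gained it and 82 turned direction without being called both times. Scaling moved the median of all genes: for 20 ppb, 40 ppb and 80 ppb against control by -0.14, -0.16 and -0.03 with quantile normalization, -0.34, -0.37 and -0.16 with the median, 0.07, 0.16 and -0.03 with normexp and -0.71, -0.86 and 0.07 with spike-in scaling, and for 80 against 40 ppb by 0.11, 0.22, -0.20 and 0.94. The no-filter setting moved the medians against control by 0.18, 0.31 and 0.06. Signal over background limits dim genes: 390, 456 and 266 calls at 20, 40 and 80 ppb had a lower group well above background on neither array. The causes of the shifts listed here were not tested, except that a stricter filter tests fewer genes and a smaller fit has fewer arrays. A fit of 4 arrays also takes its spread from the 2 groups compared alone. The count for 80 against 20 ppb rose there from 2443 to 6021, so fewer arrays alone do not account for these shifts.

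With normexp background the counts were 1219, 3099 and 303 genes at 20, 40 and 80 ppb against control, 96 for 40 against 20 ppb, 2670 for 80 against 40 ppb, 990 for 80 against 20 ppb and 96 shared by all doses, with 17 lists at 20 ppb; the falls of omd and tefb at 40 ppb turned to 0.105 and 0.109. With no filter they were 2011 at 20 ppb, 739 at 80 ppb, 259, 1986 and 1195 between doses in that order and 342 shared, with 14 lists at 80 ppb. The filter on all 8 arrays gave 872 at 80 ppb, 415 shared and 16 lists at 20 ppb, and left hccsa.1 at 20 ppb with another probe at 3.6; the mean of all probes gave hccsa.1 1.656 and ptgs2b at 40 ppb -0.376. A minimum of 2-fold left 2752 for 80 against 40 ppb. In the authors' table abcc1 at 40 ppb was 0.198. With only the 4 arrays compared the counts were 1333, 0 (limma, 4737 at an unadjusted p under 0.05) and 628 against control, 1 (2049 at an unadjusted p under 0.05), 58 and 6021 between doses in the same order, and 0 shared. A replicate block gave 2418, 4076 and 891 against control, 316, 2844 and 1567 between doses and 415 shared. Lists past camera with an estimated correlation were 0, 0 and 0 at 20, 40 and 80 ppb.

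Spike-in scaling gave 6591 and 8483 genes at 20 and 40 ppb against control, 8063 for 80 against 40 ppb and 6406 for 80 against 20 ppb, with 5 lists at 20 ppb and 9 at 40 ppb. It turned called genes to slc2a2 -0.1, chia.4 -0.002, epcam -0.08 and casp6a -0.041 at 20 ppb, and to etfa -0.194, sesn3 -0.041, amy2al2 -0.124, ghra -0.07 and igfbp5b -0.183 at 40 ppb, where vtg1, not called before (0.277), passed at -0.583 (adjusted p = 0.0498). Array brightness as a covariate gave 12369, 13322 and 8199 against control, 8284, 12629 and 11713 between doses and 3942 shared, with 14 lists at 80 ppb. The crossed pairing gave 8966 at 20 ppb against control, 1426 for 40 against 20 ppb and 8821 for 80 against 20 ppb, and pairing by number in the same 4 arrays 1618, 409 and 5233.

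Leaving out each array gave 606 to 3932 genes at 20 ppb: 1508 and 1782 without control replicates 1 and 2, 606 and 756 without 20 ppb replicates 1 and 2, and 1528 without either 80 ppb replicate. At 40 ppb it gave 2313 to 6282: 2313 and 3252 without control replicates 1 and 2, 3028 without either 20 ppb replicate and 2590 without either 80 ppb replicate. At 80 ppb it gave 91 to 1598: 609 and 512 without control replicates 1 and 2, 631 without either 20 ppb replicate, and 91 and 100 without 80 ppb replicates 1 and 2. For 40 against 20 ppb it gave 41 to 741: 41 and 62 without the 20 ppb replicates, 339 without 40 ppb replicate 2 and 153 without either 80 ppb replicate. For 80 against 40 ppb it gave 118 to 6353: 1596 without either 20 ppb replicate, 1939 without 40 ppb replicate 2, and 118 and 152 without the 80 ppb replicates. For 80 against 20 ppb it gave 103 to 3181: 152 and 201 without the 20 ppb replicates and 103 and 128 without the 80 ppb replicates. Genes shared by all doses numbered 45 to 703: 307 and 293 without the control replicates, 227 and 237 without the 20 ppb replicates and 45 without either 80 ppb replicate. Lists numbered 8 to 10 at 20 ppb, 11 to 18 at 40 ppb and 6 to 11 at 80 ppb, the 11 being without control replicate 2, and the pool fits had 0 genes (limma) throughout.

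For the trend across pools all 8 arrays with no pool term gave 27 genes, the random block 0 (limma, 637 at an unadjusted p under 0.05), leaving out the 20 ppb pool 51 and slide row as a covariate 25. For exposed pools they gave 644, 119, 109 and 104, and leaving out the 40 ppb pool gave 252. Fits on 3 pools and those with the slide row have 1 residual degree of freedom before moderation.

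Some list calls were lost under a setting other than the estimated correlation. At 20 ppb DNA repair had an adjusted p of 0.106 with quantile normalization, 0.0503 with the filter on all arrays, 0.1 with array brightness as a covariate, 0.0855 without control replicate 1 and 0.06 without 20 ppb replicate 1, ovary 0.104 without control replicate 2, collagens 0.0707 with the filter on all arrays and 0.0547 with array brightness, and skin 0.0542 without control replicate 2, 0.0709 with scaling to the median and 0.0532 with the mean of all probes. At 40 ppb complement had 0.0853 and 0.0982 without control replicate 2 and 40 ppb replicate 1, ribosomal proteins 0.119 and 0.151 without control replicate 1 and 40 ppb replicate 2 and 0.106 with scaling to the median, germ cell 0.0571 with quantile normalization, glucocorticoid response 0.0824 and 0.0891 without control replicate 2 and 40 ppb replicate 1 and 0.21 with quantile normalization, 0.0968 with scaling to the median, 0.15 with the filter on all arrays and 0.0763 with array brightness, and intestine 0.0541 without 40 ppb replicate 1. At 80 ppb gluconeogenesis had 0.0583 without control replicate 1 and 0.0582 without 80 ppb replicate 2, and muscle 0.107, 0.0618 and 0.0568 without control replicate 1 and 80 ppb replicates 1 and 2, 0.0765 with quantile normalization and 0.0631 with the filter on all arrays. With spike-in scaling liver, muscle, skin, collagens and DNA repair at 20 ppb and skin, intestine, complement, ribosomal protein, germ cell and glucocorticoid lists at 40 ppb lost their calls.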

Other observations

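All tests of explanations in this part were chosen only after the results were seen. Several groups outside the calls held genes that changed strongly. Of 27 inflammation genes 7 rose and 1 fell at 20 ppb and 9 rose and 1 fell at 40 ppb (camera adjusted p = 0.244 and 0.304). The collagenase mmp13a fell by 3.04 at 20 ppb, where the leukotriene enzyme alox5a rose by 2.86, the cyclooxygenase ptgs2b by 2.22 and the chemokine cxcl8a by 1.85; at 40 ppb ptgs2b rose by 1.74 with its brightest probe and stood at -0.38 with the mean of all probes. Immediate early genes, which respond within minutes to stimulation, rose in 8 of 34 and fell in none at 20 ppb (adjusted p = 0.085; median 0.38, -0.34 with spike-in scaling), with egr2a at 2.95, dusp2 at 2.02 and klf2b at 1.99, while at 80 ppb 1 rose and 4 fell (0.0628), with klf4 at -2.43 (at least 3.56-fold) and nr4a3 at -1.75. Of 21 fatty acid synthesis genes 6 rose and none fell at 20 ppb (0.196), among them thrsp (2.25), agpat2 (1.96), elovl2 (1.77) and the desaturase scdb (1.57). In glycolysis 8 of 29 rose and 1 fell at 20 ppb (0.085), led by the neuronal enolase eno2 (2.41), which the nerve list also holds, and by glucokinase gck (1.45), which rose by 2.74 at 80 ppb. Estrogen response genes split at 20 ppb, 1 higher and 2 lower of 14 (0.146), as vtg4 rose by 3.25 while nots fell by 2.75 and the receptor esr2b by 2.40.

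Respiratory chain genes rose in 7 of 76 and fell in 1 at 20 ppb and rose in 11 and fell in 2 at 40 ppb (camera adjusted p = 0.0728 and 0.093), with ndufs8b at least 9.39-fold and 7.65-fold higher and ndufb11 at 3.92 and 4.26 (control well above background on 1 array). Antioxidant enzymes went both ways, 2 up and 2 down of 18 at 20 ppb (0.933): the peroxiredoxin prdx4 fell by 2.40 and gpx8 by 1.34, whereas gpx4b rose by 1.38. Lymphocyte markers had 5 up and 2 down of 15 at 20 ppb (0.424), with the T cell coreceptor cd8a at least 3.25-fold lower (-2.59), the B cell factor pax5 at -1.55 and the T cell receptor partner cd28 at 1.35. Of the xenobiotic list 8 rose and 4 fell of 33 at 40 ppb (0.27), with aldh3a2b at least 3.69-fold higher (2.16), cyp2k16 at 1.74 and cyp1c1 at 1.55, and at 80 ppb cyp3a65 fell by 1.45 and tiparp by 1.41, unlike cyp1a. The sterol list had 3 of 24 lower at 80 ppb (0.131), among them ldlra (-1.70) and mvda (-1.01). Median, mean and camera direction differed in sign for the skin list at 80 ppb (-0.09, 0.06 and down), the adipose list at 40 ppb (0.46, -0.03 and up) and the clock list at 40 ppb (0.06, -0.02 and down).

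The first pattern is the rise of eye, pituitary and nerve markers in pools of fish whose heads were removed. Array brightness is argued against, since with it as a covariate the head and nerve medians at 20 ppb were 1.441 and 1.566. An effect that grows with dose is argued against only under the main scaling, where the head median was -0.788 from 20 to 80 ppb. With spike-in scaling it was 0.001, which does not decide. That comparison sets 1 pool against 1 pool, and no list passed there with an estimated correlation (smallest camera adjusted p = 0.107). Head tissue left on the exposed bodies stays open for 20 and 40 ppb, where the lowest of the 6 medians of lens, photoreceptor and pituitary genes was 1.107. There 10 and 9 of 10 lens, 7 and 6 of 15 photoreceptor and 4 and 3 of 5 pituitary genes rose. These genes are members of the head list whose rise prompted the test. Their medians show that the rise was not limited to 1 of these tissues, but cannot tell head tissue from another source. At 80 ppb the medians were 0.107 for lens, 0.443 for photoreceptor and 1.709 for pituitary genes, which whole head tissue would not give, though a part near the pituitary stays open. Differences in nervous tissue with exposure and between the 3 fish of each pool were not tested.

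The next pattern is that of genes measured 16-fold or more from control, although in 41 of 62, 65 of 81 and 35 of 56 such calls at 20, 40 and 80 ppb the lower group was not above background, so many of these folds are not exact. Sequence differences under single probes are argued against for genes with other probes, as 77.4% (41 of 53) had another probe called the same way, and 12 of 19 where the 16-fold holds against background, but stay open for genes with 1 probe. An exposure effect shared by the doses is argued against as a full account, as 39.7% (58 of 146) were called the same way at all doses, and 21 of 52 where the 16-fold holds. MHC haplotypes that differ between the fish of the pools may account for mhc1uha, psmb8f and psmb9b: of 12 other genes of such haplotypes, chosen after values were seen, 8 (66.7%) were called at 4-fold or more at some dose, against 6.8% of named genes, but linked genes are not independent, so no p is given, and an immune response to exposure stays open. As an example, psmb8f stood at 0.23, -0.59, -6.67 and -0.20 in the control, 20, 40 and 80 ppb pools and psmb8a at 0.88, 1.13, 3.62 and 0.36; whether the other 16-fold genes differ for a like reason, or with exposure at 1 dose, was not tested.

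The last pattern is that the 20 and 40 ppb pools were alike and the 80 ppb pool lay nearer control. Array brightness in part ran with this split. The 75th percentile of the signal was 357.9 and 608.6 at 20 ppb and 701.1 and 237 at 40 ppb. It was 826.2 and 686.4 at 80 ppb and 1062.3 and 427.7 in control. The main axis of difference between arrays (first principal component, 51.4% of variance) ran from -0.497 on the brightest array to 0.634 on the dimmest. Counts of genes argue against brightness as the full source only narrowly. Genes that differed numbered 4281 between 80 and 40 ppb and 633 between 40 and 20 ppb. With brightness as a covariate they numbered 12629 and 8284, just past the limit set for this test, with 8199 between 80 ppb and control. The counts alone therefore do not decide it. With that covariate the liver and muscle medians from 40 to 80 ppb remained at -0.85 and -0.94, though they were -0.09 and -0.06 with spike-in scaling. The row of the slide is argued against as the main source in the main fit only. There 633 genes differed between 40 and 20 ppb, which lie in different rows, and 3169 between 20 ppb and control, which share one. With brightness as a covariate these counts were 8284 and 12369, which do not meet the limit set for this test. A 20 ppb replicate 2 taken from the 80 ppb group, as its description would have it, is argued against by a Spearman correlation across genes of 0.9842 with 20 ppb replicate 1 and at most 0.952 with the 80 ppb arrays. A response that does not grow with dose, and differences in tissue make-up, sex or genotype between the fish of the pools, stay open and untested with 1 pool per dose.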
